A study of Mus musculus with 9 samples.

How the data were processed

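Whole eyes of 3 inbred mouse strains, A/J, BALB/c and C57BL/6J, were profiled by RNA sequencing of poly(A) RNA. Per the labels' protocols, eyes were enucleated from female mice of 4 weeks, RNA was purified on columns with DNase treatment, and each library was prepared from pooled RNA of 5 mice after random-primed cDNA synthesis. There were 3 libraries per strain and 9 in all. Each library is named here by its strain and its replicate number. The labels do not say whether the libraries of a strain came from different pools of mice or from 1 pool. The p-values therefore measure the spread between libraries, which may be partly or wholly technical.

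The authors deposited 1 table per library with 13089 genes, a gene symbol, a description, a functional category and a value with 2 decimals. Per the submitters' processing notes, CASAVA 1.7 and GenomeStudio were used with the mouse genome build mm9. The counting rule, gene models and read length are not given in the sources used here. The file headers name no unit. The deposited values were taken as RPKM, which divides a gene's reads by its length and by the library's mapped reads, because the sum of value times transcript length came to between 99.3% and 101.7% of the total that RPKM gives in 8 libraries and to 117.3% of it in C57BL/6J 3. The smallest of the genes' highest strain means was 0.997 RPKM, so the deposited tables appear to list genes that reached a mean of 1 RPKM in at least 1 strain. A gene listed at 0 can be a failed estimate, and 71 genes were at 0 in at least 1 library.

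The depth of the libraries is unknown. A search for a depth at which low values become whole reads found at most 52.4% of values within 0.1 of a whole number of reads, no more than the highest share in 50 shuffles of gene lengths in the same library, so reads were not recovered and no counting interval can be given. The sum of RPKM over all listed genes, which is not a depth, ranged from 511888 to 599635.

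Values were divided by median-of-ratios size factors (0.932 to 1.156), 0.5 was added, and log2 was taken. A gene was tested if it reached 1 RPKM in at least 3 libraries, which kept 12920 genes and left out 169. Differences between strains were tested with limma 3.58.1 in R 4.3.3 (linear model with a trended prior variance and robust estimation), with strain as the only term and all 9 libraries in 1 fit, so that the strains shared an estimate of the spread. The tests were two-sided with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. Log2 changes are therefore on the log2(scaled RPKM + 0.5) scale, which understates changes of low genes. Means and SDs are of the deposited RPKM over 3 libraries, and the error of a log2 change is its standard error (SE) from limma. The comparisons were A/J minus C57BL/6J, BALB/c minus C57BL/6J, A/J minus BALB/c, and an F test of any difference among the 3 strains. All adjusted p-values printed for genes are from this limma test.

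Gene lists for eye cell types, other tissues that an enucleated eye can carry, immune groups and stress groups were fixed before the data were examined, as were the tests, their alternatives and the rule for naming genes. Of 657 list genes, 544 were found in the tables. The 26 lists with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over all 78 tests of lists and comparisons. A count of list members is given over all genes tested and, where so stated, adjusted over the list alone. With a correlation estimated from the data, no list passed in any comparison, and those p-values are given beside each list that passed with the preset value.

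The rule named, per comparison, the 8 largest rises and 8 largest falls among called genes with a log2 change of at least 1, no overlap between the libraries of the 2 strains and a mean of at least 2 RPKM in the higher strain, passing over clone names. It added up to 2 members of each list by smallest adjusted p among those under 0.05, and genes that check strain labels. The rule also asked for members by highest mean where none passed, but that part was not carried out. Some further genes were chosen after their values were seen. They are Cerkl, Wdfy1, Cck, Npy and Oxt, called genes named again in another comparison, and further called list members where a list had few. The cone genes Opn1sw, Opn1mw, Arr3 and Gnat2, which were not called, were also named outside the rule. Sex-linked genes and Hc were not analysed here. Some genes that the rule named are not reported here.

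The reference genome used here, with its GENCODE annotation, is of another build than mm9. It served only for current symbols, transcript length, GC content and shared sequence, and no coordinates are given. Length and GC content were found for 12842 genes (98.1%). A gene was taken as sharing sequence when at least 20% of the 31-mers of its transcripts were also found at another annotated locus, which held for 684 genes. How reads shared by several loci were counted is unknown, so levels of such genes, of genes in multigene families such as the MHC, and of overlapping genes are uncertain.

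The gene test was tried on simulated data for A/J minus C57BL/6J with 12920 genes and 200 changed genes in each of 5 draws. It recovered 56% of genes changed by 1 on the log2 scale and 89.8% of those changed by 2, and 4.2% of its calls were false. A list shifted by 0.5 was recovered in 5 of 5 draws, and 0 lists were called without a shift. The simulated noise was independent between genes and between libraries. It held none of the shifts of whole libraries seen in these data, so these rates do not measure the errors made here. Overlaps between comparisons that share libraries were set beside 20 simulations without effects, in which at most 1 gene was called in a comparison, and beside the overlap of independent sets of calls.

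The alternatives were values as deposited without scaling, quantile normalization, scaling without lens genes, a pseudocount of 0.1 or 1, no filter or 5 RPKM in at least 3 libraries, limma without trend and robust estimation, a test against a fold of 1.5, fits of only the 2 strains compared, the replicate number as a block, the estimated inter-gene correlation, and leaving out each library. Added after seeing the data were a correction of each library for GC content by a spline with 6 degrees of freedom, that correction with the replicate block, genes without shared sequence only, and leaving out A/J 3 with C57BL/6J 3 or A/J 1 with A/J 2. Unless a loss is stated, each call described for a comparison held in all 9 fits that left out 1 library. Functional categories are those of the authors' deposited tables. Plots were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.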

Results

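Poly(A) RNA of whole eyes was compared between 3 inbred mouse strains that, by the stated design, differ in how fast the retina degenerates. A/J and BALB/c are albino strains and C57BL/6J is pigmented. Each strain had 3 libraries, each from pooled RNA of 5 female mice of 4 weeks. Expression was given as RPKM for 13089 genes, and 12920 were tested. The depth of the libraries is unknown. The p-values measure the spread between libraries, and whether the libraries of a strain came from different pools is not stated. Lens crystallins dominated the eye transcriptome, taking 42.2% to 45.1% of the RPKM sum in A/J, 48.9% to 50.1% in BALB/c, and 37.1%, 43.9% and 29.6% in C57BL/6J 1, 2 and 3.

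Libraries of a strain were not equally alike. Spearman correlations across genes, which are not independent replicates, were 0.99 to 0.996 within BALB/c, but 0.916 to 0.99 within A/J and 0.91 to 0.981 within C57BL/6J. The median within-strain SD of a gene was 0.26 in A/J, 0.1 in BALB/c and 0.25 in C57BL/6J on the log2 scale. A/J 1 and A/J 2 lay at -42.4 and -51.4 on the first principal component, which held 49.1% of the variance, whereas A/J 3 lay at 7.3, near C57BL/6J 2 (8.2) and BALB/c (2.6, 14.8 and 12.4), and C57BL/6J 3 at 56.4. GC-rich transcripts were lower in A/J 1 and A/J 2, with Spearman correlations across genes of -0.65 and -0.72 between a gene's deviation and its GC content, against 0.46 in A/J 3. Trends with GC content were not confined to A/J. The correlations were 0.1, 0.56 and 0.56 in BALB/c 1, 2 and 3, and -0.3, 0.24 and 0.39 in C57BL/6J 1, 2 and 3.

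**Figure D1:**
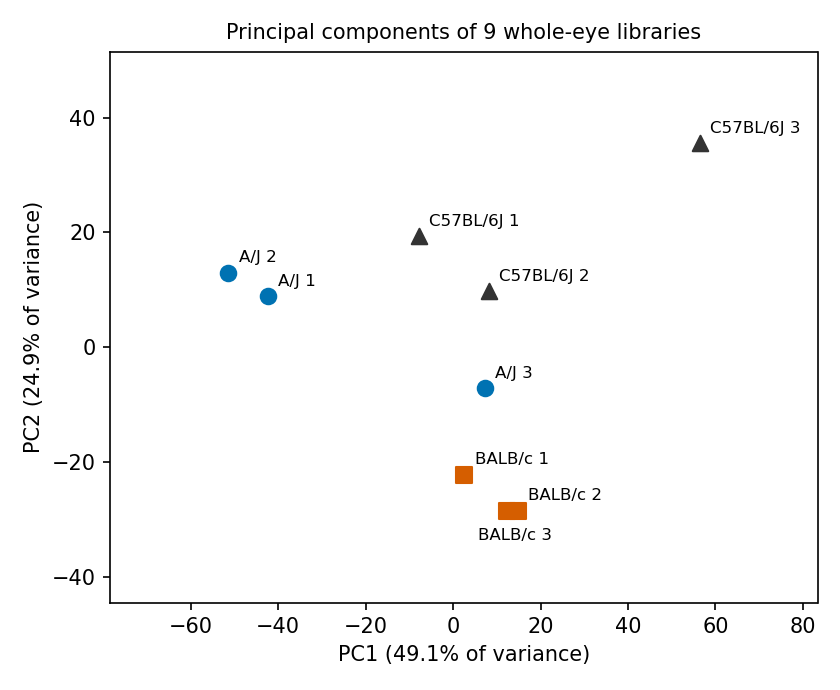
Each point is 1 of the 9 libraries on principal components 1 and 2 of the scaled log2 values, with the share of variance on each axis and strains by shape and colour. The BALB/c libraries lie together, A/J 3 (7.3 on component 1) lies apart from A/J 1 (-42.4) and A/J 2 (-51.4), and C57BL/6J 3 lies at 56.4.

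**Figure D2:**
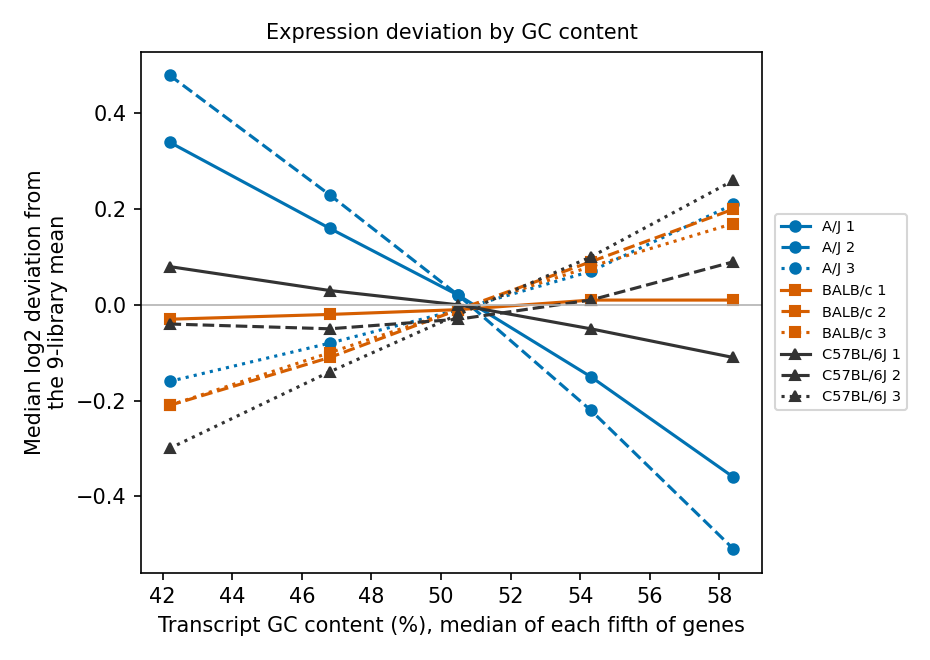
Median log2 deviation of genes from their mean over the 9 libraries, in 5 equal groups of genes ordered by transcript GC content (%). Lines are libraries, coloured by strain. A/J 1 falls from 0.34 to -0.36 and A/J 2 also falls, while A/J 3 rises with GC content.

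Myelin genes, a group chosen after the data were seen, also varied between libraries of a strain. Mobp, which encodes a protein of oligodendrocyte myelin, was at 25, 6.51 and 6.66 RPKM in the A/J libraries, at 2.88, 7.29 and 4.59 in BALB/c, and at 4.23, 7.13 and 0.01 in C57BL/6J. It was not called in any comparison.

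Genes that differ between these strains by known alleles were examined as a check of the labels. H2-Ea, whose promoter is deleted in C57BL/6, was listed at 0 in all C57BL/6J libraries, at 0.99 ± 0.312 RPKM (SD, n = 3) in A/J and at 6.39 ± 0.346 in BALB/c. Nnt, which carries a deletion in C57BL/6J, was lowest there, at 4.43 ± 0.612 RPKM against 9.26 ± 1.1 in A/J and 6.66 ± 0.085 in BALB/c. Dysf, disrupted by an insertion in A/J, was at 0.433 ± 0.11 RPKM in A/J, 1.14 ± 0.0902 in BALB/c and 1.21 ± 0.389 in C57BL/6J. Its calls were not stable: against C57BL/6J (adjusted p = 0.041) it was kept among the 9 omissions only without A/J 3 or C57BL/6J 1 (otherwise up to 0.19) and was lost after GC correction (0.055). Against BALB/c (0.027) it was lost without A/J 1, A/J 2 or any BALB/c library (up to 0.15). Tyr, the tyrosinase gene mutated in albino strains, was not called at the mRNA level (18.9 ± 2.98, 22.1 ± 1.58 and 20.3 ± 4.61 RPKM in A/J, BALB/c and C57BL/6J), except that after GC correction it was called lower in A/J than in BALB/c (log2 change -0.84, adjusted p = 0.021).

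In A/J eyes, compared with C57BL/6J, several interferon-induced genes stood higher, and a cone phosphodiesterase, a lens protein, surface epithelial keratins and myocilin stood lower. Ifi44 was at 12.9 ± 4.34 RPKM in A/J and 0.6 ± 0.246 in C57BL/6J (log2 change 3.63, SE 0.28, adjusted p = 0.00019). Pde6c, the catalytic subunit of the cone phosphodiesterase, was at 4.37 ± 0.582 against 23.7 ± 8.57 RPKM (log2 change -2.16, SE 0.21, adjusted p = 0.00072). Krt15, a keratin of basal surface epithelium, was at 50.4 ± 5.28 against 583 ± 333 RPKM (log2 change -3.26, SE 0.3, adjusted p = 0.00049). In all, limma called 348 genes, 138 higher and 210 lower in A/J, 214 of them with a log2 change of at least 1, and 2260 genes had an unadjusted p under 0.05. The count was 159 without A/J 1, 224 without A/J 2, 3651 without A/J 3, 230 without BALB/c 3, 231 without C57BL/6J 1, 127 without both A/J 1 and A/J 2, and 5132 without both A/J 3 and C57BL/6J 3. After correction for GC content it was 492, 254 higher and 238 lower, and in a fit of only these 2 strains it was 142. The 348 calls rest on a spread pooled with BALB/c, which is not in this comparison. Its median within-strain SD was 0.1, against 0.26 in A/J and 0.25 in C57BL/6J. Calls lost in the fit of 2 strains therefore did not stand on the spread of the strains compared. Of the called genes named for this comparison, Gad2 was lost with values as deposited (as were the chemokine and immediate early lists), Klf2, Isg20 and Dysf with quantile normalization. With only these 2 strains, Sag, Cabp5, C1qb, Il1r2, Nnt, Ctsl, Fn1, Npas2, Klf2, Dysf, Gsto1, Gad2, Tnfrsf1a and Isg20 were lost.

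The 8 largest rises were those of the predicted gene EG433182, Gbp1, H28, Ifi44, Sox30, Rtkn2, the predicted gene EG667977 and Otor, with log2 changes from 5.27 to 2.76. Gbp1, an interferon-induced GTPase, was at 9.6, 9.68 and 4.34 RPKM in A/J and at 0, 0 and 0.01 in C57BL/6J. Sox30, a transcription factor, was at 7.7 ± 0.587 against 0.29 ± 0.115 RPKM, and Rtkn2 at 8.16 ± 1.32 against 0.453 ± 0.0981. EG433182 shared 88.2% of its 31-mers with other loci and EG667977 shared 26.3%. Of the 8 largest falls, 7 were ribosomal protein genes and the remaining one was Atp6v0c, a proton pump subunit that shared 35.2% of its 31-mers (log2 change -4.94, adjusted p = 0.00093). Adh6a, an alcohol dehydrogenase, fell from 14.4 ± 2.86 to 0.133 ± 0.104 RPKM (log2 change -4.46).

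Among retinal cell lists in A/J minus C57BL/6J, the 14 cone genes were lower as a group (median -0.25, camera adjusted p = 0.038, and adjusted p = 0.46 with an estimated correlation), with 1 member called, Pde6c, and 3 lower when adjusted over the list alone. The median of the other 13 was -0.11, from -0.7 to 0.31. The cone list no longer passed without A/J 3 (-0.29, adjusted p = 0.39) or C57BL/6J 1 (-0.33, adjusted p = 0.13), and its median was -0.16 without C57BL/6J 3. The cone opsins Opn1sw (119 ± 25 and 125 ± 7.86 RPKM) and Opn1mw (54.7 ± 0.893 and 63 ± 14.5) were not called. Their log2 changes were 0.01 and -0.07. Arr3 (-0.57) and Gnat2 (0.08) of the same list were not called either. Of 23 rod genes, 1 was called: Sag, rod arrestin, rose from 1220 ± 81.8 to 2460 ± 411 RPKM (log2 change 1.11, adjusted p = 0.0065, or 0.07 in the fit of only these 2 strains). The rod list did not pass (median -0.28, adjusted p = 0.086). Of 12 bipolar cell genes, Prkca, the protein kinase C that marks rod bipolar cells, fell from 16.2 ± 0.787 to 6.19 ± 0.119 RPKM (log2 change -1.21, adjusted p = 0.00045). Cabp5, a calcium-binding protein of bipolar cells, rose (log2 change 1.27, adjusted p = 0.017), and its call was lost without A/J 1, A/J 2 or C57BL/6J 2 (adjusted p up to 0.09) and with only these 2 strains (0.11). Of 21 amacrine, horizontal and ganglion cell genes, the neurofilament genes Nefl (56.2 ± 1.74 against 117 ± 3.49 RPKM) and Nefm (11.7 ± 0.726 against 24.1 ± 2.16) fell, the latter with an adjusted p of 0.1 after GC correction. Gad2, a GABA-synthesising enzyme, rose (log2 change 0.71, adjusted p = 0.031), a call kept among the 9 omissions only without A/J 3 (adjusted p otherwise up to 0.1) and absent with only these 2 strains (0.19). No gene was called among 19 genes of retinal pigment epithelium and visual cycle, 17 of Mueller glia and astrocytes, or 17 of reactive gliosis, where list-alone adjustment gave 1 higher, 0 changed, and 1 higher with 4 lower. Of 17 melanocyte genes, Mc1r, the melanocortin receptor, rose (log2 change 0.99, adjusted p = 0.0049). None of these last 6 lists passed camera.

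The 25 lens genes rose slightly as a group in A/J minus C57BL/6J (median 0.31, camera adjusted p = 0.026, and adjusted p = 0.85 with an estimated correlation), although the only called member, Gluld1, a lens-specific glutamine synthetase relative, fell from 1630 ± 320 to 394 ± 38.1 RPKM (log2 change -1.93, adjusted p = 0.00074). The lens list no longer passed without A/J 3 (0.28, adjusted p = 0.35), C57BL/6J 1 (0.29, adjusted p = 0.09) or C57BL/6J 3 (0.11, adjusted p = 0.35), nor with quantile normalization (adjusted p = 0.39), and its median was 0.52 without C57BL/6J 2. Of 19 corneal and conjunctival genes, 3 fell: Krt15, Krt13 (31.8 ± 1.58 against 239 ± 92.6 RPKM) and Krt4 (7.76 ± 2.05 against 60.8 ± 31.3), keratins of stratified epithelium. Adjusted over the list alone, 5 of these genes were lower and 2 higher, and the list did not pass (adjusted p = 0.39). The 21 muscle, 5 lacrimal and Harderian gland and 7 blood genes held no called member and did not pass. The 19 vascular endothelium and pericyte genes fell as a group (median -0.36, camera adjusted p = 0.00033, and adjusted p = 0.31 with an estimated correlation), with 0 called over all genes and 3 lower when adjusted over the list alone. Of 29 extracellular matrix genes, Myoc, which encodes myocilin, fell from 58.6 ± 9.21 to 12.1 ± 1.29 RPKM (log2 change -2.12, adjusted p = 0.00029). Fn1, fibronectin, rose (log2 change 0.79, adjusted p = 0.013), and its call was lost without A/J 1 (0.081) and with only these 2 strains (0.11).

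The list of 37 interferon-response genes was higher in A/J as a group (median 0.64, camera adjusted p = 2.8e-13, and adjusted p = 0.42 with an estimated correlation): 13 were called higher and 1 lower, or 20 and 2 when adjusted over the list alone. Oas2, an antiviral oligoadenylate synthetase, was at 5.08 ± 1.23 against 0.837 ± 0.29 RPKM (log2 change 2.14, adjusted p = 0.00049), and the ubiquitin-like modifier Isg15 at 39.6 ± 12.5 against 11.9 ± 3.04. The lower member, Isg20, an exonuclease, had a log2 change of -0.79 (adjusted p = 0.025), lost without A/J 1, A/J 2, BALB/c 2, C57BL/6J 1 or C57BL/6J 2 (adjusted p up to 0.1) and after GC correction (0.25). For the interferon response list, A/J minus C57BL/6J, the median without A/J 1 and A/J 2 was 0.26 and the list still passed. Among 23 MHC and antigen presentation genes, 5 were higher (H2-Ea, H2-Q2, H2-Q6, H2-Q10 and H2-T10) and 7 lower, and the list did not pass (adjusted p = 0.39). H2-Ab1, a class II chain, was at 3.71 ± 0.517 against 19.6 ± 4.62 RPKM, and H2-Eb1 at 3.17 ± 1.1 against 12.2 ± 1.24. The genome to which reads were mapped derives from C57BL/6J, and these genes vary in sequence between strains. The 23 chemokine, cytokine and receptor genes fell as a group (median -0.20, camera adjusted p = 0.038, and adjusted p = 0.54 with an estimated correlation), a result lost without A/J 3 (-0.23, adjusted p = 0.39) or C57BL/6J 1 (-0.17, adjusted p = 0.21) and among genes without shared sequence (0.099). Its 3 called members, all lower, were Ccl27, of whose 31-mers 79.8% were shared (log2 change -2.50), the decoy interleukin receptor Il1r2 (-1.67) and the tumour necrosis factor receptor Tnfrsf1a (-0.56). Il1r2 was lost without A/J 1, C57BL/6J 1 or C57BL/6J 3 (adjusted p up to 0.065). Tnfrsf1a was lost in 7 of 9 omissions, all but those of A/J 3 and C57BL/6J 3 (up to 0.13), and after GC correction (0.22). Of 25 microglia and macrophage and 16 complement genes, C1qb was the 1 called in each (log2 change -0.73, adjusted p = 0.022), lost without A/J 1, A/J 2, BALB/c 3, C57BL/6J 1 or C57BL/6J 2 (up to 0.088) and after GC correction (0.18), and neither list passed.

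Of 46 oxidative stress genes in this comparison, Nnt rose (log2 change 1.09, adjusted p = 0.0058, or 0.063 in the fit of only these 2 strains) and Gpx3, a secreted glutathione peroxidase, fell from 206 ± 83 to 29.6 ± 1.96 RPKM (log2 change -2.59, adjusted p = 0.00034). Gsto1, a glutathione transferase, fell from 2580 ± 743 to 906 ± 235 RPKM (adjusted p = 0.022), a call lost without A/J 1, BALB/c 3, C57BL/6J 1 or C57BL/6J 3 (up to 0.075) and with only these 2 strains (0.12). Of 31 phagocytosis and lysosome genes, Myo7a, the motor myosin of photoreceptors and pigment epithelium, fell from 5.48 ± 0.856 to 1.83 ± 0.391 RPKM (adjusted p = 0.0022). Ctsl, cathepsin L, rose (log2 change 1.03, adjusted p = 0.025), a call kept among the 9 omissions only without A/J 3 or C57BL/6J 1 (otherwise up to 0.13). Npas2 of 18 clock genes fell (log2 change -1.17, adjusted p = 0.0083, or 0.069 with only these 2 strains), as did Hspa8 of 20 heat shock genes, which shared 79.7% of its 31-mers (log2 change -2.05). Immediate early genes, 19 in number, were lower as a group (median -0.24, camera adjusted p = 0.049, and adjusted p = 0.85 with an estimated correlation). The immediate early list, A/J minus C57BL/6J, did not pass after GC correction (0.45) or without A/J 2 (-0.18, adjusted p = 0.17), A/J 3 (-0.47, 0.063), BALB/c 3 (-0.24), C57BL/6J 1 (0.21) or C57BL/6J 3 (0.062). Its 1 called member, Klf2, an endothelial transcription factor (log2 change -0.72, adjusted p = 0.046), kept the call among the 9 omissions only without A/J 3 or BALB/c 1 (otherwise up to 0.22) and lost it after GC correction (0.43). The oxidative stress, phagocytosis, extracellular matrix, clock and heat shock lists did not pass, nor did the 9 replication-dependent histone genes, none of which was called. Median, mean and camera direction differed in sign for the corneal (0.01, -0.37, lower), oxidative stress (0.09, -0.03, higher), heat shock (0.12, -0.03, higher) and histone lists (-0.03, 0.05, lower).

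**Figure D3:**
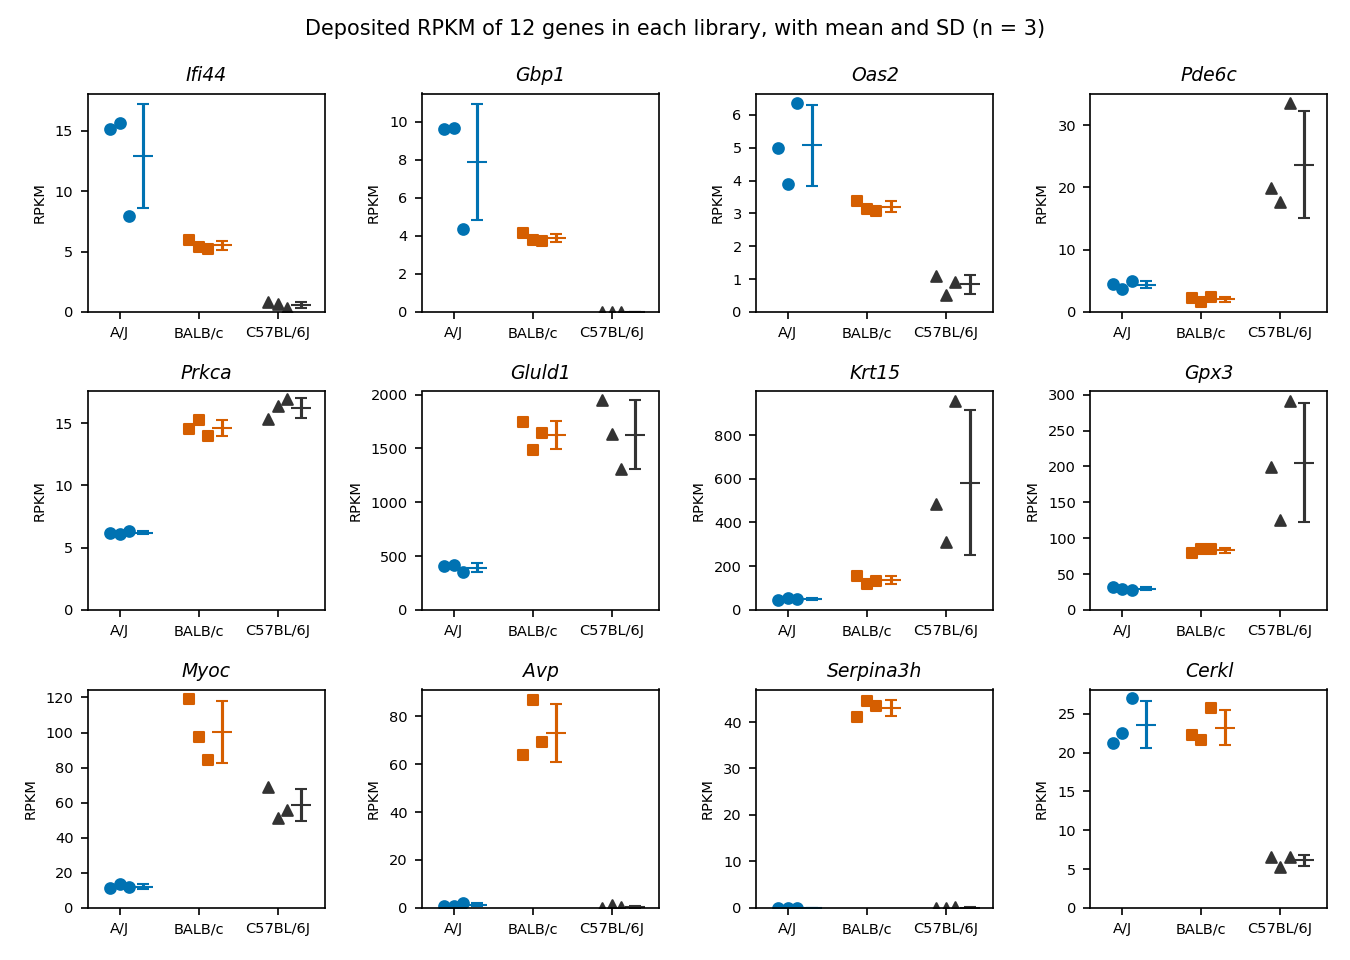
Deposited RPKM of 12 genes, each panel a gene with the 3 libraries of each strain as points and the mean with SD as a bar beside them. Ifi44, Gbp1 and Oas2 are lowest in C57BL/6J, Pde6c is highest there, Prkca and Gluld1 are lowest in A/J, and Avp and Serpina3h are high in BALB/c.

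In BALB/c eyes, compared with C57BL/6J, vasopressin and a serine protease inhibitor stood out as higher, and the lens list was higher and the cone list lower with the preset correlation of camera but not with an estimated one (adjusted p = 0.46 and 0.31). Avp, the vasopressin gene, was at 73.2 ± 12.1 RPKM in BALB/c and 0.443 ± 0.551 in C57BL/6J (log2 change 6.55, SE 0.39, adjusted p = 3.4e-05). Oxt, which encodes the related hormone oxytocin, was at 3.68 ± 1.02 against 0.353 ± 0.422 RPKM (adjusted p = 0.011, lost without BALB/c 2 or BALB/c 3, up to 0.064). Serpina3h was at 43 ± 1.77 against 0.08 ± 0.0458 RPKM (log2 change 6.33, SE 0.12, adjusted p = 1.3e-08). Its deposited description names this member in words but gives Serpina3a, another member of this gene family, as the symbol in brackets. How much of the sequence of Serpina3h is shared with other loci was not measured, so its level is uncertain. Pde6c was at 2.03 ± 0.44 against 23.7 ± 8.57 RPKM (log2 change -3.06, SE 0.21, adjusted p = 8.3e-05). There were 396 called genes, 247 higher and 149 lower in BALB/c, 240 with a log2 change of at least 1, and 1774 had an unadjusted p under 0.05. With values as deposited the count was 381, 156 higher and 225 lower, since the median of all genes then shifted by -0.17. It was 639 without A/J 3, 221 without BALB/c 1, 181 without BALB/c 2, 166 without BALB/c 3, 222 among genes without shared sequence, and 1920 without both A/J 3 and C57BL/6J 3. Of the called genes named for this comparison, Mt2, Nnt and Lypd2 were lost both with values as deposited and with quantile normalization, Myoc and Hspe1 with values as deposited and Cfp with quantile normalization. With only these 2 strains, Mt2, Nefl, Cryga, Actn3, Hspe1, Hist1h4h, Nnt, Gpx3, Lypd2 and Isg20 were lost.

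Besides Avp, Serpina3h and H2-Ea, the largest rises included those of Atp5l, EG433182, ENSMUSG00000059775 and Rpl36, ribosomal or mitochondrial genes and predicted genes with related copies in the genome. Atp5l, an ATP synthase subunit that shared 69.6% of its 31-mers, was at 70.7 ± 15.4 against 0.82 ± 1.19 RPKM. Of the 8 largest falls, 6 were ribosomal protein genes, and the others were Adh6a (0.193 ± 0.0306 against 14.4 ± 2.86 RPKM) and Pbp2, a phosphatidylethanolamine-binding protein (0.23 ± 0.0954 against 15.4 ± 5.06). Zhx2, a transcriptional repressor, fell from 6.81 ± 0.202 to 0.793 ± 0.0603 RPKM (log2 change -2.36, adjusted p = 3.7e-05). Npy, neuropeptide Y, rose from 27.8 ± 0.506 to 69.6 ± 7.01 RPKM (log2 change 1.48, adjusted p = 0.00027).

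The 14 cone genes were lower in BALB/c than in C57BL/6J as a group (median -0.38, camera adjusted p = 0.0009, and adjusted p = 0.31 with an estimated correlation), with Pde6c called and 2 lower when adjusted over the list alone. The median of the other 13 was -0.33, from -0.7 to 0.18. Among them Arr3 had a log2 change of -0.7, Gnat2 -0.43, Opn1mw -0.3 and Opn1sw 0.02. The 21 amacrine, horizontal and ganglion cell genes were also lower (median -0.23, camera adjusted p = 0.043, and adjusted p = 0.46 with an estimated correlation), a result lost without A/J 3 (0.058), BALB/c 1 (0.078), C57BL/6J 1 (0.13) or C57BL/6J 2 (-0.15, adjusted p = 0.09). Its 1 called member, Nefl (68.1 ± 4.6 against 117 ± 3.49 RPKM, adjusted p = 0.034), lost the call in 7 of 9 omissions, all but those of A/J 3 and C57BL/6J 3 (up to 0.17). The 17 melanocyte genes were higher (median 0.19, camera adjusted p = 0.04, and adjusted p = 0.8 with an estimated correlation), with Mc1r called (3.53 ± 0.32 against 1.32 ± 0.193 RPKM). The melanocyte list was lost without A/J 3 (0.063), BALB/c 3 (0.054) or C57BL/6J 3 (0.09, adjusted p = 0.26) and with quantile normalization (0.13), and its median was 0.01 with values as deposited. No rod gene of 23 was called, and 2 were higher when adjusted over the list alone. No called gene was found among 19 pigment epithelium and visual cycle or 17 Mueller glia and astrocyte genes. Of 17 gliosis genes, Serpina3n, an acute-phase protease inhibitor of reactive astrocytes, fell from 31.4 ± 1.79 to 9.04 ± 0.532 RPKM (adjusted p = 0.0009), and the metallothionein Mt2 rose (log2 change 0.75, adjusted p = 0.034). The deposited description of Serpina3n names this member in words but gives Serpina3a as the symbol in brackets. That of Serpina3h, which went the other way, does the same. Serpina3n shared 21.6% of its 31-mers with other loci, so its level is uncertain. For Serpina3h this share was not measured, so its level is uncertain too. Gng13, a G protein subunit of ON bipolar cells, rose among 12 bipolar genes (log2 change 0.73, adjusted p = 0.015). Mt2 lost the call in 6 of 9 omissions, all but those of A/J 3, BALB/c 1 and C57BL/6J 1 (up to 0.19), and Gng13 without any BALB/c library or C57BL/6J 1 (up to 0.093) and after GC correction (0.11). None of these last 5 lists passed.

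Lens genes were higher in BALB/c than in C57BL/6J as a group of 25 (median 0.79, camera adjusted p = 2e-12, and adjusted p = 0.46 with an estimated correlation), with 2 called over all genes and 14 higher when adjusted over the list alone. Cryga, a gamma crystallin, was at 18600 ± 1480 against 3230 ± 2740 RPKM (log2 change 3.07, adjusted p = 0.017), and Grifin, a lens fibre galectin relative, at 1020 ± 35.2 against 511 ± 101. The list's median was 0.31 with quantile normalization (adjusted p = 0.038). Cryga lost its call without any BALB/c library or C57BL/6J 1 (up to 0.085), and Grifin without BALB/c 2 or BALB/c 3 (up to 0.061) and after GC correction (0.055). Of 19 corneal and conjunctival genes, Krt13 (67.5 ± 5.35 against 239 ± 92.6 RPKM), Krt15 (137 ± 18 against 583 ± 333) and Krt4 (11.3 ± 0.713 against 60.8 ± 31.3) fell and Lypd2 rose (log2 change 1.04, adjusted p = 0.043). Krt15 was lost without BALB/c 2 or BALB/c 3 (up to 0.084), Krt4 without BALB/c 3 (0.053), and Lypd2 in 6 of 9 omissions, all but those of A/J 2, A/J 3 and C57BL/6J 3 (up to 0.2). Of 21 muscle genes, the myoglobin gene Mb (162 ± 27.8 against 411 ± 110 RPKM) and Actn3, of fast muscle fibres, fell. Mb was lost without BALB/c 2, BALB/c 3, C57BL/6J 1 or C57BL/6J 3 (up to 0.13), and Actn3 in 6 of 9 omissions, all but those of A/J 2, A/J 3 and C57BL/6J 3 (up to 0.15), and after GC correction (0.069). Of 29 matrix genes, Myoc rose (100 ± 17.6 against 58.6 ± 9.21 RPKM, adjusted p = 0.022), a call lost without BALB/c 1, BALB/c 2 or C57BL/6J 2 (up to 0.11). No gene was called among 5 gland, 7 blood or 19 vascular genes. The corneal, muscle, matrix, gland, blood and vascular lists did not pass.

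Interferon-response genes were higher in BALB/c than in C57BL/6J as a group of 37 (median 0.25, camera adjusted p = 0.0011, and adjusted p = 0.82 with an estimated correlation), with 9 higher and 3 lower, or 13 and 4 when adjusted over the list alone. The median was 0.39 without C57BL/6J 1 and 0.09 with values as deposited. Ifi44 was at 5.5 ± 0.378 against 0.6 ± 0.246 RPKM, Ifi27 at 34.5 ± 5.31 against 13.8 ± 1.81, and Isg15 at 37.4 ± 4.39 against 11.9 ± 3.04. Gbp1, outside this list, was at 3.89 ± 0.22 RPKM in BALB/c. The lower members were Ifi204 (log2 change -1.27), Ifit3 (-1.33) and Isg20 (-0.77), each lost in some omissions. Ifi204 was lost without A/J 1, any BALB/c library, C57BL/6J 1 or C57BL/6J 3 (up to 0.17). Ifit3 was lost without BALB/c 2, BALB/c 3 or C57BL/6J 1 (up to 0.097), and Isg20 without A/J 1, BALB/c 2, BALB/c 3, C57BL/6J 1 or C57BL/6J 2 (up to 0.14) and after GC correction. The 25 microglia and macrophage genes were lower as a group (median -0.40, camera adjusted p = 0.0084, and adjusted p = 0.66 with an estimated correlation), though not without C57BL/6J 1 (-0.25, adjusted p = 0.072). The 16 complement genes were lower too (median -0.21, camera adjusted p = 0.027, and adjusted p = 0.66 with an estimated correlation), though not without C57BL/6J 1 (-0.13, adjusted p = 0.21) or C57BL/6J 2 (0.063) or among genes without shared sequence (0.058). C1qb, a subunit of the complement initiator C1q and a member of both lists, had a log2 change of -0.72, lost without any BALB/c library, C57BL/6J 1 or C57BL/6J 2 (up to 0.14). Cfp, properdin, had -0.55, lost in all omissions except that of A/J 3 (up to 0.24) and after GC correction (0.085). The 23 chemokine, cytokine and receptor genes were lower (median -0.32, camera adjusted p = 0.00048, and adjusted p = 0.31 with an estimated correlation), with Ccl27 called (-1.95) and 5 lower when adjusted over the list alone. Of 23 MHC genes, 5 were higher and 6 lower and the list did not pass. H2-Q10 was at 3.57 ± 0.624 against 0.107 ± 0.0981 RPKM and H2-Eb1 at 4.18 ± 0.928 against 12.2 ± 1.24, the latter lost without BALB/c 1, BALB/c 2 or C57BL/6J 1 (up to 0.085).

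The 46 oxidative stress genes were higher in BALB/c than in C57BL/6J (median 0.19, camera adjusted p = 0.0065, and adjusted p = 0.82 with an estimated correlation), with 5 higher and 2 lower, or 9 and 2 when adjusted over the list alone. The list did not pass without C57BL/6J 3 (0.08, adjusted p = 0.087), and its median was 0.01 with values as deposited. The higher members were the glutathione transferases Gstm2 (22.3 ± 1.47 against 10.3 ± 0.581 RPKM), Gstp1 and Gstp2, of whose 31-mers 67.5% and 78.1% were shared, Mt2 and Nnt. The lower ones were Gpx3 (82.9 ± 3.2 against 206 ± 83) and Gsto1 (767 ± 64.9 against 2580 ± 743). Gstp1 was lost without BALB/c 2 or BALB/c 3 (up to 0.069), Gsto1 without any BALB/c library (up to 0.074). Nnt was lost in 7 of 9 omissions, all but those of A/J 3 and C57BL/6J 1 (up to 0.2). Gpx3 was lost in 7, all but those of A/J 3 and C57BL/6J 2 (up to 0.17). Of 31 phagocytosis genes Myo7a fell (log2 change -0.73, adjusted p = 0.039), kept among the 9 omissions only without A/J 2 or A/J 3 (otherwise up to 0.18). Of 20 heat shock genes Hspa8 fell (-0.92) and Hspe1 rose (0.76), the latter lost in 7 of 9 omissions, all but those of A/J 3 and C57BL/6J 2 (up to 0.19). Hspa8 shared 79.7% and Hspe1 48.1% of their 31-mers with other loci. No clock gene of 18 and no immediate early gene of 19 was called, and these 4 lists did not pass. The 9 replication-dependent histone genes, whose mRNA mostly lacks a poly(A) tail and which served as a check of poly(A) selection, were higher as a group (median 0.94, camera adjusted p = 0.022, and adjusted p = 0.31 with an estimated correlation), with a median of 0.53 without C57BL/6J 1 and an adjusted p of 0.058 after GC correction. Hist1h4h, of which 50% was shared, was its called member (log2 change 1.15), lost without A/J 1, BALB/c 2, BALB/c 3 or C57BL/6J 2 (up to 0.15) and after GC correction (0.062). Median and mean differed in sign for the bipolar (-0.02, 0.14), corneal (0.09, -0.17), MHC (-0.01, 0.21) and phagocytosis (0.01, -0.06) lists, where camera followed the mean.

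**Figure D4:**
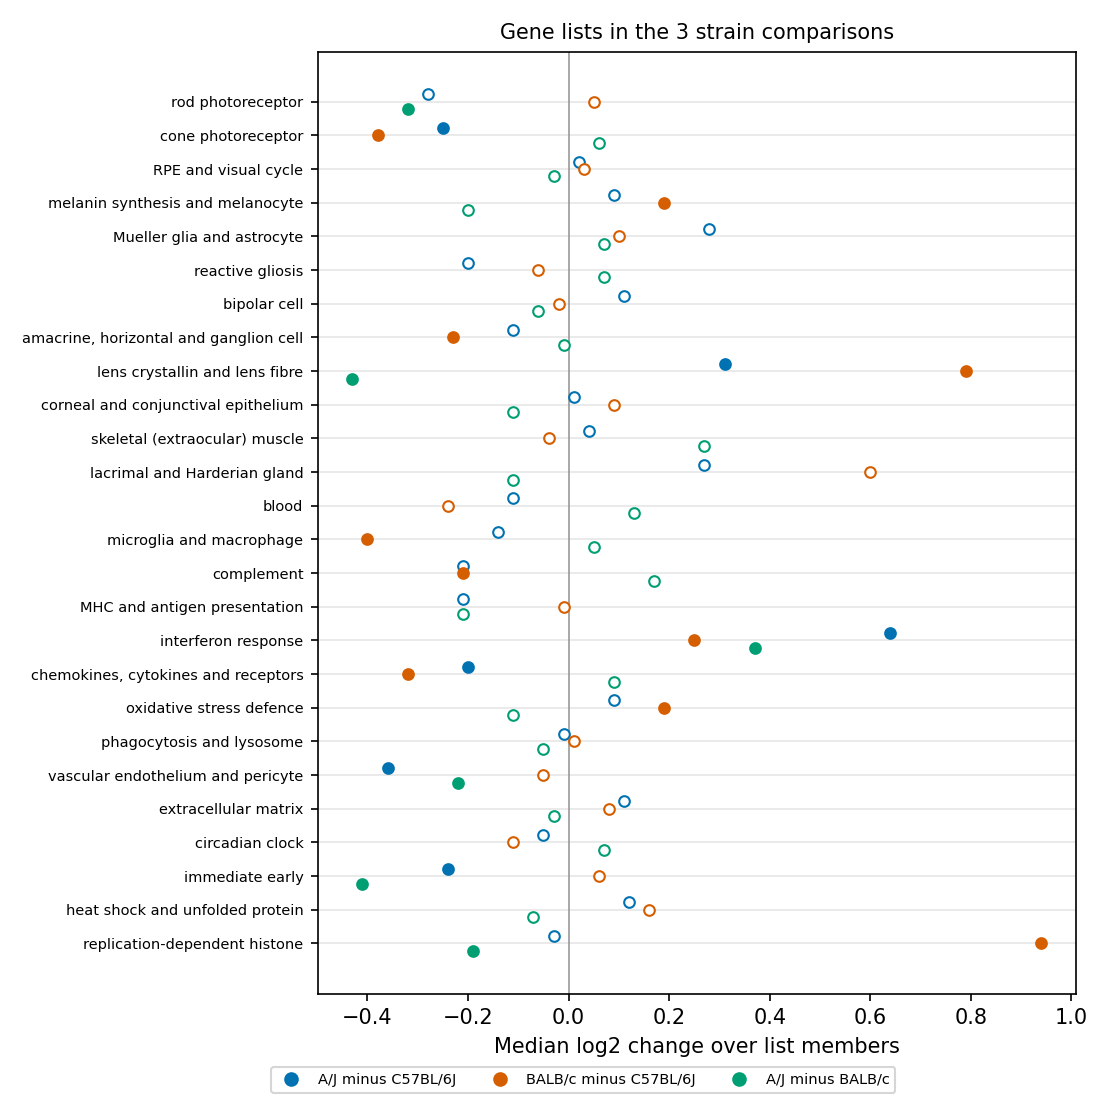
Median log2 change over the members of each of the 26 lists, coloured by comparison. Filled points passed camera with the preset correlation (adjusted p under 0.05) and open ones did not, and none passed with an estimated correlation. The interferon list lies at 0.64, 0.25 and 0.37, and the lens list at 0.31, 0.79 and -0.43, in A/J minus C57BL/6J, BALB/c minus C57BL/6J and A/J minus BALB/c.

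Between the albino strains, A/J eyes had less myocilin, vasopressin and lengsin mRNA than BALB/c eyes. The interferon list was higher with the preset correlation but not with an estimated one (adjusted p = 0.66), with 3 of 37 members called. Myoc was at 12.1 ± 1.29 RPKM in A/J and 100 ± 17.6 in BALB/c (log2 change -3.06, SE 0.18, adjusted p = 5.5e-05). Gluld1, which encodes lengsin, was at 394 ± 38.1 against 1620 ± 130 RPKM (log2 change -2.11, SE 0.19, adjusted p = 0.00083). Prkca was at 6.19 ± 0.119 against 14.6 ± 0.632 RPKM (log2 change -1.24, SE 0.11, adjusted p = 0.00081). There were 319 called genes, 73 higher and 246 lower in A/J, 201 with a log2 change of at least 1, and 2705 had an unadjusted p under 0.05. With values as deposited the count was 282, 95 higher and 187 lower. It was 134, 162 and 4477 without A/J 1, 2 and 3, 166, 114 and 106 without BALB/c 1, 2 and 3, 606 without C57BL/6J 3, 148 among genes without shared sequence, 74 without both A/J 1 and A/J 2, and 7742 without both A/J 3 and C57BL/6J 3. Of the called genes named for this comparison, Guca1a, Vwf and Dysf were lost both with values as deposited and with quantile normalization, Krt13 and Krt15 with values as deposited, Abca8a, Crygf, Hspb1 and Usp18 with quantile normalization (as was the histone list), and Vwf and Usp18 with only these 2 strains.

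The 8 largest rises were those of Rps2, Pglyrp4, Zhx2, Otor, Edn2, Itpa, Krt16 and Rab37. Zhx2 was at 6.71 ± 1.18 against 0.793 ± 0.0603 RPKM (log2 change 2.43, adjusted p = 6.5e-05), Otor, otoraplin, at 18.9 ± 6.33 against 3.48 ± 0.964, and Edn2, endothelin 2, at 5.65 ± 2.31 against 0.813 ± 0.0929. Pglyrp4 was lost without A/J 1, A/J 2, BALB/c 2 or BALB/c 3 (up to 0.066), and Krt16, whose description in the tables is that of Krt17, without A/J 1 or BALB/c 2 (up to 0.057). Rps2, Krt16 and Itpa shared 77.2%, 51.9% and 34.6% of their 31-mers with other loci, so their levels are uncertain. The largest falls included those of Atp5l, listed at 0 in all A/J libraries, Rps3a, Serpina3h (0.04 ± 0.0173 against 43 ± 1.77 RPKM), Avp (1.25 ± 0.609 against 73.2 ± 12.1), Rpl36 and Rpl9, the last lost without A/J 1, A/J 2 or any BALB/c library (up to 0.13). Sequence shared by Serpina3h with other loci was not measured, so its level is uncertain here as well. Npy was at 31.4 ± 1.56 against 69.6 ± 7.01 RPKM (log2 change -1.20, adjusted p = 0.0016).

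The 23 rod genes were lower in A/J than in BALB/c as a group (median -0.32, camera adjusted p = 0.035, and adjusted p = 0.31 with an estimated correlation), with 1 called and 7 lower when adjusted over the list alone. The rod list was lost without A/J 3 (-0.29, adjusted p = 0.22) or BALB/c 1 (-0.34, adjusted p = 0.066), and with quantile normalization its median turned to 0.04 (adjusted p = 0.85). Its called member, Guca1a, an activator of photoreceptor guanylate cyclase, was at 432 ± 62 against 670 ± 37.1 RPKM (adjusted p = 0.048), kept among the 9 omissions only without A/J 3, C57BL/6J 2 or C57BL/6J 3 (otherwise up to 0.24) and lost after GC correction (0.15). No cone gene of 14 was called (list median 0.06), nor any of 19 pigment epithelium and visual cycle or 17 melanocyte genes. The melanocyte list, which did not pass, did so after GC correction (adjusted p = 0.0092), and without that correction had an adjusted p of 0.85 with an estimated correlation. Prkca was the called gene of 12 bipolar genes. Abca8a, a glial transporter, rose among 17 Mueller glia and astrocyte genes (log2 change 0.78), kept among the 9 omissions only without A/J 3 or C57BL/6J 3 (otherwise up to 0.21). Gad2 rose among 21 amacrine, horizontal and ganglion cell genes (0.74), kept only without A/J 3, C57BL/6J 1 or C57BL/6J 3 (otherwise up to 0.16). Of 17 gliosis genes, Edn2 and Serpina3n (18 ± 3.39 against 9.04 ± 0.532 RPKM, 21.6% shared) rose and Mt2 (49.6 ± 5.77 against 119 ± 16.6) and Bcl3 fell. Serpina3n was lost in 6 of 9 omissions, all but those of A/J 3, C57BL/6J 1 and C57BL/6J 3 (up to 0.13), and Bcl3 without A/J 1, A/J 2, BALB/c 2 or BALB/c 3 (up to 0.15) and after GC correction (0.53). The lists from cone to gliosis did not pass.

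Lens genes were lower in A/J than in BALB/c as a group of 25 (median -0.43, camera adjusted p = 0.00026, and adjusted p = 0.82 with an estimated correlation), with Gluld1 and Crygf called and 4 lower when adjusted over the list alone. With quantile normalization the lens median was -0.06 (adjusted p = 0.39). Crygf, a gamma crystallin of which 49.6% was shared, was at 1540 ± 188 against 7110 ± 281 RPKM (adjusted p = 0.04), kept among the 9 omissions only without A/J 3, C57BL/6J 2 or C57BL/6J 3 (otherwise up to 0.17) and lost after GC correction (0.07). The 19 vascular genes were lower (median -0.22, camera adjusted p = 0.013, and adjusted p = 0.31 with an estimated correlation), a result lost without A/J 3 (-0.32, adjusted p = 0.083), and the median was -0.11 without A/J 1. Its called member was Vwf, the von Willebrand factor gene (log2 change -0.95, adjusted p = 0.048), kept among the 9 omissions only without A/J 3 or C57BL/6J 3 (otherwise up to 0.23), with 5 lower when adjusted over the list alone. Of 19 corneal and conjunctival genes, Krt13 (31.8 ± 1.58 against 67.5 ± 5.35 RPKM), Krt15 and Sfn fell, each lost in some omissions. Krt13 was lost without A/J 1, A/J 2 or any BALB/c library (up to 0.16), Krt15 also without C57BL/6J 1 (up to 0.17) and after GC correction (0.053), and Sfn without A/J 1, A/J 2, BALB/c 2 or BALB/c 3 (up to 0.11) and after GC correction (0.15). Actn3 rose among 21 muscle genes (11.1 ± 0.537 against 5.52 ± 0.711 RPKM), lost without A/J 1, A/J 2 or any BALB/c library (up to 0.13). The muscle list, which did not pass, did so after GC correction (adjusted p = 0.014), and without that correction had an adjusted p of 0.85 with an estimated correlation. Among 29 matrix genes, Fn1 rose (19 ± 1.64 against 9.81 ± 0.456 RPKM, lost without A/J 1, BALB/c 2 or BALB/c 3, up to 0.078) and Myoc fell. No called gene was found among 5 gland or 7 blood genes, and the corneal, matrix, gland and blood lists did not pass.

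Interferon-response genes were higher in A/J than in BALB/c as a group of 37 (median 0.37, camera adjusted p = 1e-05, and adjusted p = 0.66 with an estimated correlation), with 3 higher and 0 lower, or 14 and 1 when adjusted over the list alone. The median was 0.62 without A/J 3 and 0.19 without A/J 1 and A/J 2. Oasl2, an oligoadenylate synthetase relative, was at 18.6 ± 3.56 against 6.27 ± 0.275 RPKM (log2 change 1.41, adjusted p = 0.0069). The other called members were Ifi204 (1.41), lost without A/J 1, A/J 2 or any BALB/c library (up to 0.13), and Usp18 (0.66), kept among the 9 omissions only without A/J 3 or C57BL/6J 3 (otherwise up to 0.22). Ifi204 shared 46% of its 31-mers with other loci, so its level is uncertain. Of 23 MHC genes, H2-Ea, H2-Ab1 (3.71 ± 0.517 against 11.5 ± 2.38 RPKM) and H2-T23 (9.19 ± 0.82 against 22.5 ± 1.27) fell. No gene was called among 25 microglia and macrophage, 16 complement or 23 chemokine genes. The 4 lists did not pass, though that of microglia and macrophages did after GC correction (adjusted p = 0.029). With an estimated correlation and no GC correction its adjusted p was 0.85. Of 46 oxidative stress genes, 5 fell: Mt2, Gstm2 (9.69 ± 1.92 against 22.3 ± 1.47 RPKM), Gstp1, Gstp2 and Gpx3 (29.6 ± 1.96 against 82.9 ± 3.2), with Gstp1 and Gpx3 each lost without BALB/c 2 or BALB/c 3 (up to 0.053). Npas2 of 18 clock genes fell (log2 change -1.03), lost without any BALB/c library (up to 0.1). Hspa8 and Hspb1 of 20 heat shock genes fell (-1.14 and -1.19), the latter lost after GC correction (0.3) and kept among the 9 omissions only without A/J 3, C57BL/6J 2 or C57BL/6J 3 (otherwise up to 0.22). Hspa8 shared 79.7% and Hspb1 58.4% of their 31-mers with other loci. No phagocytosis gene of 31 was called, and these 4 lists did not pass.

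Immediate early genes, 19 with none called, were lower in A/J than in BALB/c (median -0.41, camera adjusted p = 0.038, and adjusted p = 0.84 with an estimated correlation), with 3 lower when adjusted over the list alone. That result was lost after GC correction (0.2) and without A/J 2 (-0.27, adjusted p = 0.081), A/J 3 (0.063), BALB/c 2 (0.11) or C57BL/6J 1 (0.05). The 9 histone genes, the check of poly(A) selection, were lower (median -0.19, camera adjusted p = 0.049, and adjusted p = 0.42 with an estimated correlation), lost without A/J 3 (-0.34, adjusted p = 0.29), BALB/c 1 (0.066) or C57BL/6J 1 (0.054) and after GC correction (0.067), with a median of -0.32 without A/J 2. Its called members were Hist1h4c, lost without A/J 1, A/J 2, BALB/c 1 or BALB/c 2 (up to 0.069), and Hist1h4h, lost without A/J 1, A/J 2, BALB/c 2 or BALB/c 3 (up to 0.096) and after GC correction (0.11). In this comparison median and mean or camera direction differed in sign for the pigment epithelium (-0.03, 0.04, higher), matrix (-0.03, -0.05, higher), clock (0.07, -0.03, higher) and phagocytosis lists (-0.05, 0.01, lower).

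Ribosomal protein genes, a family singled out after the values were seen, made up many of the largest changes. Of 80 tested, 21 were higher and 7 lower in BALB/c than in C57BL/6J (median 0.65, or 0.28 after removal of a trend with transcript length), 0 higher and 9 lower in A/J than in C57BL/6J (median -0.16), and 1 higher and 26 lower in A/J than in BALB/c (median -0.91), with medians of the same sign for values as deposited and after quantile normalization. Rpl26 was at 160 ± 38.3 RPKM in C57BL/6J, 0.437 ± 0.48 in A/J and 1.5 ± 0.42 in BALB/c, and Rps3a at 73 ± 15 in C57BL/6J, 63 ± 9.57 in BALB/c and 0.267 ± 0.0987 in A/J. Of these genes 70 shared at least 20% of their 31-mers with other loci, as did Rpl26 (55%) and Rps3a (76.9%), so their levels are uncertain. Among all tested genes with such shared sequence, the F test called 20.7%, against 3.5% of the others.

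Across the 3 strains, the F test called 576 genes (4.5%). Genes called in the same direction in A/J and BALB/c against C57BL/6J numbered 158, 66 higher and 92 lower. Cerkl, a ceramide kinase-like gene linked to retinal dystrophy, was at 23.6 ± 3.05 RPKM in A/J and 23.2 ± 2.21 in BALB/c but 6.12 ± 0.696 in C57BL/6J (adjusted p = 7.4e-05 and 4.8e-05), and Wdfy1 at 12.8 ± 1.52, 10.5 ± 0.331 and 3.03 ± 0.416. Cck, cholecystokinin, was at 7.19 ± 1.26, 13 ± 0.624 and 29.9 ± 4.62 RPKM in A/J, BALB/c and C57BL/6J. Ifi44, Isg15, Gbp1, Sox30 and Mc1r were among those higher in both albino strains, and Pde6c, Adh6a, Krt13, Krt15, Gpx3 and Hspa8 among those lower. Of 160 genes called in both comparisons, 2 went opposite ways, Myoc and 4732456N10Rik. The fall of 4732456N10Rik in A/J (adjusted p = 0.027) was lost without A/J 1, A/J 2, BALB/c 1, C57BL/6J 1 or C57BL/6J 3 (up to 0.091), after quantile normalization or GC correction, and with only 2 strains. Independent sets of calls would share 2.6 higher and 2.4 lower genes, and simulations with no effect gave 0. In these simulations at most 1 gene was called in a comparison, so that 0 does not measure the overlap that shared libraries bring, and part of the 158 may come from the shared C57BL/6J libraries. The F test count was 321 without A/J 1, 4274 without A/J 3, 334, 298 and 286 without BALB/c 1, 2 and 3, 368 among genes without shared sequence, 322 without A/J 1 and A/J 2, and 7987 without A/J 3 and C57BL/6J 3. For the 158 genes the corresponding counts were 99, 273, 103, 91, 87, 102, 92 and 561.

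Genes that set A/J apart from both other strains in the same direction numbered 91, 33 higher and 58 lower. Otor and Sox30 were among the higher and Prkca, Gluld1, Myoc, H2-Ab1 and Gpx3 among the lower ones. Of 97 genes called in both comparisons, 6 went opposite ways, and independent sets of calls would share 0.8 higher and 4 lower genes. Simulations with no effect gave 0, with the same limit, and part of the 91 may come from the shared A/J libraries. The count was 33, 43 and 2555 without A/J 1, 2 and 3, 48, 35 and 34 without BALB/c 1, 2 and 3, 60 without C57BL/6J 2, 54 among genes without shared sequence, 21 without A/J 1 and A/J 2, and 4270 without A/J 3 and C57BL/6J 3.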

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

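The GC correction, its combination with the replicate block, genes without shared sequence, and the omission of 2 libraries together were chosen only after the results were seen. Counts of genes are given in the order A/J minus C57BL/6J, BALB/c minus C57BL/6J, A/J minus BALB/c, any strain (F test), both albino strains against C57BL/6J, and A/J against both others, with values within 1.5 times of those of the report left out unless stated. With 5 RPKM in 3 libraries the counts were 182 and 222 for the comparisons with C57BL/6J, 339 for any strain, and 74 and 50 for the shared sets, fewer genes being tested. Against a fold of 1.5 they were 106, 106 and 56, then 53 and 16, a stricter null, and no F test or list test was run. The fit of only the 2 strains gave 142 for A/J minus C57BL/6J, the comparison without the tight BALB/c libraries. It gave 394 for BALB/c minus C57BL/6J and 425 for A/J minus BALB/c. Genes without shared sequence gave 222, 148, 368, 102 and 54 from BALB/c minus C57BL/6J on. Without A/J 3 and C57BL/6J 3 the 6 counts were 5132, 1920, 7742, 7987, 561 and 4270, with 2 lists passing in each comparison with A/J. Without A/J 1 and A/J 2, where the lone A/J library is assumed to vary like the others, counts were 127, 74, 322, 92 and 21 in the comparisons with A/J and the joint sets, and 13 and 10 lists passed. With an estimated correlation 0 lists passed in A/J minus C57BL/6J, 0 in BALB/c minus C57BL/6J and 0 in A/J minus BALB/c. Omitting 1 library, the 6 counts ranged from 159 to 3651, 166 to 639, 106 to 4477, 286 to 4274, 87 to 273 and 33 to 2555, and lists passing from 2 to 7, 7 to 10 and 2 to 9. All genes called with 9 libraries in the 3 pairwise comparisons were also called without A/J 3. Tyr in A/J minus C57BL/6J, near 0 and not called, changed sign with values as deposited (-0.09), 5 RPKM (0), GC correction with or without the block (-0.42 and -0.42), without A/J 3 and C57BL/6J 3 (-0.10) and without A/J 1 and A/J 2 (-0.28), and ranged from -0.24 to 0.16 when 1 library was omitted. Dysf in BALB/c minus C57BL/6J, not called, changed sign with values as deposited (-0.04) and ranged from -0.05 to 0.21. The rod list in A/J minus BALB/c turned to 0.04 with quantile normalization. Without scaling, the median of all genes shifted by -0.11, -0.17 and 0.05 in the 3 comparisons. The cause of these changes was not tested where none is given. Of 175 named gene results, 162 stayed on their side of the threshold in the same direction with values as deposited, 160 with quantile normalization and 153 with GC correction, as did 20, 17 and 18 of 22 list results. Against a fold of 1.5 only 92 of 175 did, with only the 2 strains 148, with the block 167, with 5 RPKM 129 of 138, and among genes without shared sequence 103 of 114. The block ended the calls of Klf2 and Tnfrsf1a in A/J minus C57BL/6J, Mt2, Nefl, Cfp and Hspe1 in BALB/c minus C57BL/6J, and Vwf and Usp18 in A/J minus BALB/c. With 5 RPKM, Klf2 and Gad2, then Cfp, Nnt, Gpx3 and Lypd2, then Guca1a and Usp18 were lost in these comparisons, and Vwf with a pseudocount of 0.1. In A/J minus C57BL/6J the immediate early list did not pass with a pseudocount of 0.1 or no filter, nor the chemokine list with 5 RPKM. The melanin list in BALB/c minus C57BL/6J failed with 5 RPKM, and the histone list in A/J minus BALB/c with a pseudocount of 0.1. The GC correction gave 492, 583 and 390 genes. A pairing of the libraries by replicate number was not evident for all numbers. Of 9 libraries, 2 correlated best with their own number in both other strains, and correlations between equal numbers ran from -0.51 to 0.54. They were 0.34, 0.54 and 0.34 between libraries numbered 1, and 0.24, 0.47 and 0.09 between those numbered 3. Those numbered 2 had -0.51, 0.01 and 0.02, and unequal numbers ran from -0.67 to 0.6. A partial pairing therefore stays open. The block gave 408, 397 and 375 genes. The A/J minus C57BL/6J chemokine (adjusted p = 0.07) and immediate early (0.069), BALB/c minus C57BL/6J amacrine, and A/J minus BALB/c rod (0.064) and histone lists (0.059) no longer passed with it. Since depth is unknown, what it limits could not be measured.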

Other observations

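Chosen only after the results were seen were the myelin gene list, the tests of GC content as a share of variance, of optic nerve tissue, of shared sequence, of mismatches to the reference, of ribosomal protein genes in A/J against C57BL/6J, of the lens share in C57BL/6J 3, and of cones. The bound for GC content in C57BL/6J 3 was revised after its result, the bounds of the mismatch test were replaced 2 times after theirs, an interval was added to the bound for translation genes after its result, a first lens test whose outcome was fixed was replaced, and the optic nerve test first covered A/J 1 and A/J 2 together.

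Functional categories in the authors' tables differed in how often their genes were called among the 3 strains by the F test (23 categories, Fisher's exact test, two-sided). System process genes were called in 17.4% of cases against 4.4% of other genes (odds ratio 4.61, adjusted p = 2e-05), and in 15.6% among genes without shared sequence. Structural molecular activity genes were called in 12.3% (odds ratio 3.04, adjusted p = 0.0049). Transcription genes were called less often, in 1.9% against 4.7% (odds ratio 0.4, adjusted p = 1.1e-05). Translation genes were called in 14% against 4.2% (odds ratio 3.67, adjusted p = 2.5e-09). Translation genes with unique sequence had an odds ratio of 1.17 (95% interval 0.495 to 2.38, 8 of 196 called), too wide to tell whether they differ more often beyond those that share sequence. Metabolic process genes passed among genes without shared sequence (4.8% against 3.3%, odds ratio 1.47, adjusted p = 0.021) but not over all genes (0.063). The histone list, a check of poly(A) selection, was higher in BALB/c than in C57BL/6J (median 0.94), so a difference in that selection between these libraries, which was not tested, stays open.

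A group of 13 myelin genes, all measured in these eyes, had median log2 changes of 1.5 in A/J minus C57BL/6J, 0.58 in BALB/c minus C57BL/6J and 0.95 in A/J minus BALB/c, with none called. Single libraries carried much of this: without A/J 1 the medians were 0.94, 0.58 and 0.37, and without C57BL/6J 3 they were 0.85, -0.12 and 0.95. The BALB/c minus C57BL/6J median was 0.36 without BALB/c 2 and 1.04 without C57BL/6J 2. A few genes were high in C57BL/6J 3 alone. Atp13a4, a cation-transporting ATPase, was at 228.04 RPKM there and at most 0.94 in any other library, Pcdhgc5, a protocadherin, at 24.8 against at most 0.71, and Slc3a1, an amino acid transporter subunit, at 14.56 against at most 0.27. The globin genes Hba-a1 and Hba-a2 were at 16.38 and 16.26 RPKM in C57BL/6J 3 and listed at 0 in the others, but they shared 71.4% and 91% of their 31-mers with other loci, so these levels are uncertain. The 41 clustered protocadherin genes were higher there than in the mean of C57BL/6J 1 and 2 by a median of 1.49 on the log2 scale.

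Pde6c was lower in both albino strains, and fewer cones could lower it. The other 13 cone genes had medians of -0.11 in A/J and -0.33 in BALB/c against C57BL/6J, far smaller than the changes of Pde6c (-2.16 and -3.06). The A/J median was -0.21 without A/J 2, and -0.18, -0.23 and -0.07 without C57BL/6J 1, 2 and 3. Fewer cones as the whole cause are therefore argued against. A change of Pde6c itself, by strain or through strain variants against the reference, stays open and was not tested.

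A/J 1 and A/J 2 differed from A/J 3 across the transcriptome. GC content took 49% of the variance over genes of that difference, and GC correction reduced the calls of A/J minus C57BL/6J without A/J 3 to 33.4% of their number (from 3651 to 1221), so a GC bias of the libraries may explain part of it. The within-strain SD of A/J was 2.58 times that of BALB/c before the correction and 2.21 times after it, past the bound set beforehand against GC content as the whole cause. But BALB/c was the tightest strain, and C57BL/6J lay at 2.74 times BALB/c after the same correction. This ratio therefore cannot decide whether GC content was the whole cause. Myelin genes were higher than in A/J 3 by 1.80 in A/J 1, as more optic nerve in that library would give. The difference of 0.37 in A/J 2 leaves optic nerve there undecided. Differences between the mice pooled stay open.

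Genes that share sequence with other loci, many of them ribosomal protein genes, carried many calls. Their odds of an F-test call were 7.36 times those of other genes at equal mean level, so reads shared between loci may be involved. Reads lost by mismatches to the C57BL/6J reference could lower such genes in the other strains: 72.4% of those called were lower in A/J. But 57.9% of called genes with unique sequence were lower too (74.6% against 67% as deposited), and 90.7% of called shared genes were lower in A/J than in BALB/c, where neither strain is the reference, so this share decides nothing. In BALB/c 30.2% were lower (41.2% of unique ones, or 38.6% against 66.5% as deposited), first taken as evidence against it. Rises of other origin dilute that share, and 4.7% of shared genes were called lower against 0.9% of other genes (6.2% against 1.4% in A/J), so loss by mismatch stays open in both strains. The 10 ribosomal protein genes with unique sequence had a median of -0.63 in A/J minus BALB/c (-0.39 after GC correction and -0.42 with quantile normalization), so lower ribosomal protein mRNA as a whole stays open there, but 0.09 in A/J minus C57BL/6J (-0.02 as deposited), which argues against it in that comparison. That median was -0.02, 0.01 and 0.2 without A/J 1, 2 and 3, and 0.15 and 0 without C57BL/6J 1 and 3. In BALB/c minus C57BL/6J the same 10 genes had a median of 0.62, with 3 called higher and 0 lower. It was 0.64 after GC correction, 0.47 as deposited and 0.43 without C57BL/6J 3. For these genes BALB/c was thus the strain that stood apart, and its rise was not confined to genes with shared sequence. After removal of a trend with transcript length, the median of all 80 in BALB/c minus C57BL/6J was 0.28, between the bounds set, so length bias cannot be told apart from a strain difference.

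C57BL/6J 3 stood apart from C57BL/6J 1 and 2. Value times transcript length summed to 117.3% of the RPKM total in it, against 99.3% to 101.7% in the other libraries. Clustered protocadherin genes were higher in it, and a few genes were high in it alone. Whether its values were computed in the same way as the others is not known and was not tested. GC content took 9.6% of the variance, which argues against it as the main cause. A smaller share of lens RNA as the whole cause would move all other tissues alike. The muscle list, picked as the lowest list outside the lens, lay below the rod list by -0.70 (medians -0.71 and -0.02, quartiles -0.91 to -0.49 and -0.21 to 0.3). Some gap was expected from that choice, so it argues against the lens share as the whole cause only weakly. Genes with at least 80% shared sequence were higher in this library by 0.19 relative to unique genes, which leaves the counting of shared reads undecided. All 13 myelin genes were lower, by a median log2 difference of -2.21. Less optic nerve in this library would give this, and might come from dissection or from the mice pooled.

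Other splits of the same libraries were set beside the counts. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In A/J minus C57BL/6J, 2 splits gave as many as the real 348 genes, the highest other 4347, and 5 gave as many as the 6 lists, the highest other 10. In BALB/c minus C57BL/6J, 1 split, the real one, gave 396 genes and 10 lists, the highest others 0 and 8. In A/J minus BALB/c, 1 split, the real one, gave 319 genes, the highest other 0, and 5 gave as many as the 6 lists, the highest other 9. Of 100 splits of the 9 libraries drawn at random, 7 gave as many as 576 genes by the F test (highest other 4217) and 5 as many as the 91 that set A/J apart (highest other 1554), so chance is not excluded for these. For the 158 shared by the albino strains, 4 of 100 did (highest other 2362), which is under 0.05 by a single split of those drawn and does not firmly exclude chance. The highest splits for these 3 counts put A/J 1, A/J 2 and C57BL/6J 1 together, and several times the real count points to a structure of the samples other than strain.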
